A study of Homo sapiens with 12 samples.

How the data were processed

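RNA was measured in 12 cultures of NHA, a line of normal human astrocytes, on Affymetrix HuGene 2.0 ST arrays, which read transcripts by hybridisation to probe sets placed along each gene. Per the labels, total RNA was extracted with Qiagen miRNeasy kits, biotin-labelled and hybridised, with 3 biological replicates for each of 4 groups. The groups are the parental line, the CIC-knockout (CIC-KO) clones A2 and H9, and the ATXN1L-knockout (ATXN1L-KO) clone B82, with the knockouts made by CRISPR/Cas9.

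The deposited values are log2 probe-set summaries, 1 column per array, which the authors made with Affymetrix Expression Console. The log base is read from the range of the values and is not stated. The version, the background correction and the summarization method are not given in the sources used here, nor are the normalization between arrays and the genome build behind the probe annotation. The values were used as deposited, with no further normalization. The table holds 53617 probe sets, of which 16098 carry 1 gene symbol. The other 37519 carry no single symbol, and those with none and with several were not counted apart. For the 779 genes with more than 1 probe set, the brightest by mean over all arrays was kept, which left 14884 genes. No filter on dim genes was applied. Probe sets without a single symbol were left out of the comparisons of genes. They were counted in another fit of all 53617 probe sets, with p adjusted over all of these. The files give no detection calls, and the number of arrays limits the precision.

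All 12 arrays were fitted together with limma 3.58.1 (lmFit and eBayes, default settings, 1 mean per group) in R 4.3.3. The residual degrees of freedom were 8 and the estimated prior degrees of freedom 5.70, and the prior SD was 0.193. Contrasts were A2, H9, B82 and the mean of both CIC-KO clones against the parental line, H9 against A2, and B82 against the mean of both CIC-KO clones. All tests were two-sided. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 within its contrast, and a second count required at least a 2-fold change. Errors of fold changes are standard errors from the fit, with n = 3 arrays per group. All p values are adjusted values from limma unless another kind is named.

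The groups, contrasts, thresholds, gene lists, rule for naming genes and most alternatives were chosen before the data were examined. Genes named in the text are CIC and ATXN1L, the 12 highest and 12 lowest genes called in both CIC-KO clones with every knockout array beyond every parental array, and the 12 highest and 12 lowest chosen likewise in B82. The rule also names the 10 highest and 10 lowest genes called the same way in all 3 knockout lines, the 8 highest and 8 lowest in H9 against A2 and in B82 against CIC-KO, and up to 4 called members of each list with the largest change. Every member of the list of reported CIC targets may be named. A gene outside this rule is said to be chosen after its values were seen.

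Gene lists, 33 in number, were compiled from general knowledge and tested with limma's camera (preset correlation 0.01, adjusted over the lists of a contrast), with camera's estimated correlation and fry beside it. They are CIC complex, reported CIC targets, MAPK activity score genes, ERK phosphatases and feedback inhibitors, ETS family, immediate early genes, RAS-MAPK core components, receptor tyrosine kinases and growth factors, DNA replication, mitosis, p53 targets, interferon response, MHC class I and antigen processing, and inflammatory cytokines. The others are fibrillar collagens and matrix, matrix proteases, cadherins and integrins, Notch, Wnt, TGF-beta and YAP/TAZ targets, cholesterol synthesis, hypoxia and glycolysis, unfolded protein and integrated stress response, and cytosolic ribosomal proteins. Mitochondrial respiratory chain and the markers of astrocytes, oligodendrocytes, neurons, neural stem cells, fibroblasts, microglia and blood cells, and endothelium complete them. A list was tested only with the members that are the single symbol of a probe set. No member of the cadherin and integrin list is, so 32 lists were tested. Some of these were tested on a minority of their members. Examples are 5 of 17 for MHC class I, 8 of 29 for the respiratory chain, 6 of 17 for microglia and blood cells and 14 of 32 for fibrillar collagens and matrix. Results of a list cover its measured members only.

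The overlap of contrasts that share the parental arrays was set beside 100 simulations of unchanged groups and beside the overlap that independent lists of the same sizes give (the product of the sizes over the number of genes). For all 3 lines, the lists were the genes called in both CIC-KO clones and the calls of B82. The procedure was tested on simulated data with 200 changed genes in each of 10 runs. At a 2-fold change it found 80.3% of them in A2, 80.1% in H9 and 78.5% in B82, and at a 1.5-fold change 34.8%, 29.7% and 27.8%. Of its calls, between 4.53% and 4.91% were false in these 3 contrasts. The simulated noise was independent, with 1 SD per gene for every array. The real arrays had residual SDs from 0.162 to 0.247, and their residuals correlated between groups. The shares found and false in the real data may thus differ. Other splits of the arrays into groups of the same sizes were counted, 100 at most for each result.

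Neighbouring genes were examined with a running median of the log2 fold change over 61 genes in the order of the GRCh38.p14 annotation, among the 10195 genes whose mean lies above the median of all values. The deposited table names no build, and genes were joined to the annotation by gene identifier. A run is a stretch of at least 61 such genes whose running median stays beyond 0.2, and 100 shuffles of the gene order served as the comparison.

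Alternatives tried were quantile normalization, centring of arrays on their median, dropping the lowest 30% or 50% of genes, the mean of a gene's probe sets, eBayes with trend and robust, array weights (with statmod 1.5.0), fits on only the arrays compared, treat against a 1.2-fold change and an adjusted p under 0.01. Further alternatives were a block for replicate number, the cell line as a random block, line means as single samples, and leaving out each array in turn. Removal of the neighbouring-gene trend was added after the data had been seen. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.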

Results

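Expression was compared between NHA cells, a line of normal human astrocytes, and 3 clones derived from it in which CIC or ATXN1L had been targeted with CRISPR/Cas9. CIC is a transcriptional repressor that is inhibited by RAS-MAPK signalling, and ATXN1L is a partner protein with which it forms a complex. The 12 arrays comprise the parental line, the CIC-KO clones A2 and H9 and the ATXN1L-KO clone B82, with n = 3 biological replicates each, and their number limits the precision. Replicates are cultures of a single line, so the tests measure the spread between cultures of a line and not the spread between clones. There is 1 ATXN1L-KO clone and no edited clone without a knockout. The treatment label names transfection, puromycin selection and picking of colonies for all samples, parental ones included, so the labels do not settle whether the parental arrays come from a clone.

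The targeted genes were examined in every array before other genes. CIC (probe set 16862677, chromosome 19 in GRCh38.p14) had mean log2 values of 6.05 ± 0.32 (SD, n = 3) in parental cells, 5.78 ± 0.12 in A2, 5.79 ± 0.05 in H9 and 5.84 ± 0.07 in B82. The parental arrays read 5.86, 6.42 and 5.88, the A2 arrays 5.67, 5.77 and 5.92, the H9 arrays 5.83, 5.74 and 5.82, and the B82 arrays 5.90, 5.83 and 5.77. The log2 fold changes of CIC were -0.27 in A2 (adjusted p = 0.380), -0.26 in H9 (adjusted p = 0.550) and -0.22 in B82 (adjusted p = 0.600), each with SE 0.15. ATXN1L (probe set 16820893, chromosome 16) had means of 6.77 ± 0.14 in parental cells, 6.50 ± 0.10 in A2, 6.56 ± 0.08 in H9 and 6.65 ± 0.27 in B82. Its parental arrays read 6.65, 6.92 and 6.73 and its B82 arrays 6.95, 6.44 and 6.55. Its A2 arrays read 6.54, 6.39 and 6.58 and its H9 arrays 6.48, 6.63 and 6.58. The log2 fold change of ATXN1L in B82 was -0.12 ± 0.14 (SE, adjusted p = 0.805). Each gene has 1 probe set whose place relative to the edit is not known, and an edited gene can still be transcribed, so these levels neither show nor exclude the knockouts.

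**Figure D1:**
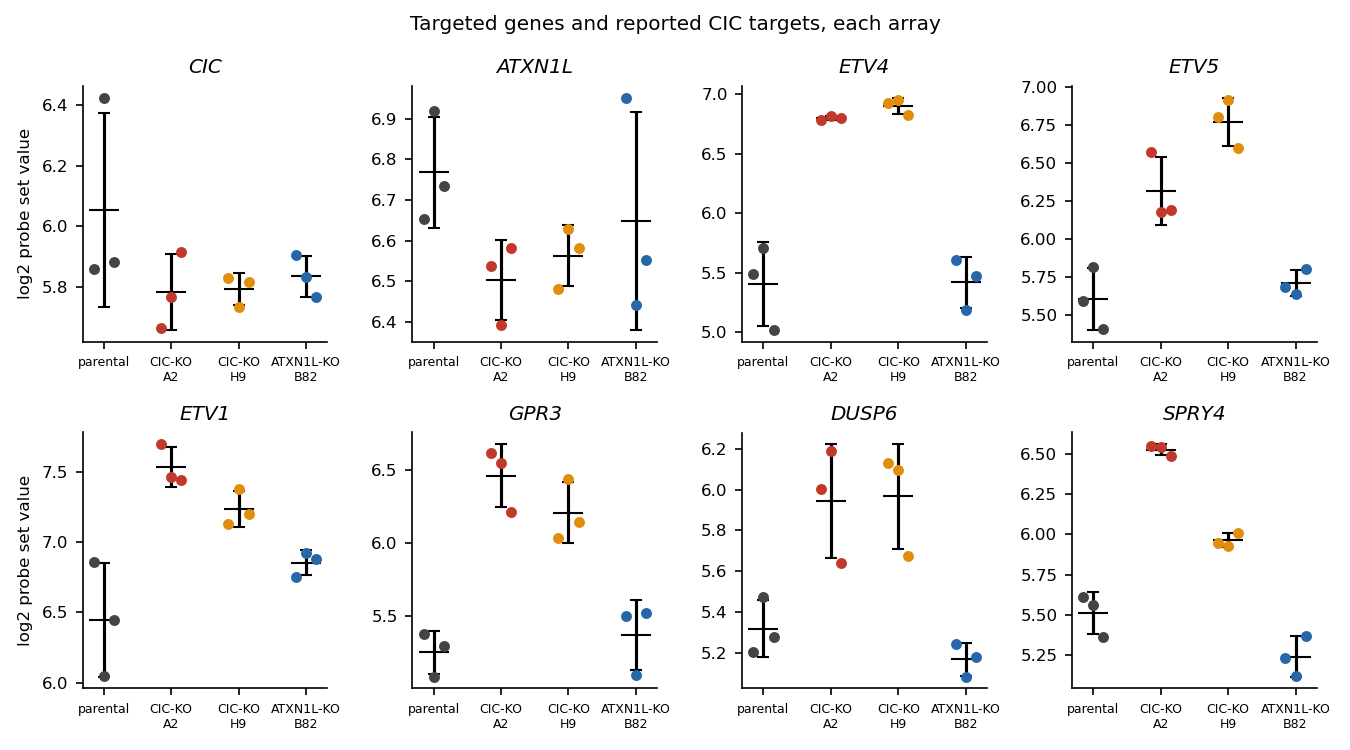
Log2 probe-set value (y axis) of CIC, ATXN1L and 6 reported CIC targets in each of the 12 arrays (points), by group (x axis: parental, CIC-KO A2, CIC-KO H9, ATXN1L-KO B82), with the group mean and SD as bars. ETV4 lies above every parental array in all 6 CIC-KO arrays, with log2 fold changes of 1.39 in A2, 1.5 in H9 and 0.02 in B82.

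The comparison of the CIC-KO clones with parental cells asks which genes change when CIC is targeted. The chemokine gene CCL2 was 35.2-fold lower in the mean of the CIC-KO clones (log2 fold change -5.14 ± 0.24 SE, n = 3 arrays per group, adjusted p = 1.17e-07), at -5.37 in A2 and -4.91 in H9. DSP, which encodes the desmosomal protein desmoplakin, was 17.9-fold lower (-4.16 ± 0.24, adjusted p = 8.85e-07), at -4.18 in A2 and -4.14 in H9. ETV4, an ETS transcription factor and reported CIC target, was 2.73-fold higher (1.45 ± 0.14, adjusted p = 0.000104), at 1.39 in A2 and 1.5 in H9. The receptor gene GPR3, another reported target, rose 2.12-fold (1.08 ± 0.14, adjusted p = 0.000947), and PDLIM3, which encodes a cytoskeletal LIM protein, rose 2.35-fold (1.23 ± 0.12, adjusted p = 0.000103). In the mean of the clones, each of these genes kept its call without any single array. That all 6 CIC-KO arrays lay beyond all 3 parental arrays follows from the rule by which they were named. The CIC-KO arrays read 2.31 to 3.26 for CCL2 and 3.38 to 4.67 for DSP, against a median of all probe sets of at least 4.31 in every array. The parental arrays of PDLIM3 read 4.07, 4.51 and 4.51, close to these medians. Such values are dim and have no measured background, so the folds of CCL2, DSP and PDLIM3 are uncertain in size.

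Further genes changed in both clones. The imprinted gene PEG10 was 4.08-fold lower (-2.03 ± 0.17, adjusted p = 3.6e-05), the neurotrophic receptor gene GFRA1 3.96-fold lower (-1.98 ± 0.18, adjusted p = 5.23e-05) and the natriuretic peptide receptor gene NPR3 3.29-fold lower (-1.72 ± 0.13, adjusted p = 1.45e-05). The matrix genes BGN (biglycan) and TNC (tenascin C) were 3.18-fold and 2.92-fold lower, with adjusted p of 0.000104 and 1.45e-05. Among the higher genes were ANXA10 (2.68-fold, adjusted p = 4.05e-05), CCN3 (2.68-fold, adjusted p = 0.000113) and IFI44L (2.5-fold, adjusted p = 0.0013). IFI44L was called in A2 at adjusted p = 0.0252, but not without parental replicate 2 (0.089), A2 replicate 1 (0.0806) or A2 replicate 2 (0.0921), or when only the arrays compared were fitted (0.0953).

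In the mean of the clones, 321 of 14884 genes were called, 100 higher and 221 lower, and 59 of them changed at least 2-fold. A2 alone had 731 called genes (219 higher, 512 lower) and H9 alone 297 (97 higher, 200 lower). Called in both clones in the same direction were 83 genes, 25 higher and 58 lower, of which 17 changed at least 2-fold in each. A further 13 genes were called in opposite directions in A2 and H9. Several counts moved by more than 1.5 times without a single array. The count in the mean fell to 201 without parental replicate 2, 173 without parental replicate 3, 209 without A2 replicate 2, 182 without H9 replicate 1, 201 without H9 replicate 2 and 207 without H9 replicate 3. The A2 count was 449 without parental replicate 3, 380 without A2 replicate 2 and 437 without A2 replicate 3. The H9 count was 166 without parental replicate 3 and 148, 144 and 150 without H9 replicates 1, 2 and 3. The count in both clones was 49 without parental replicate 3 and 54, 48 and 52 without H9 replicates 1, 2 and 3.

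**Figure D2:**
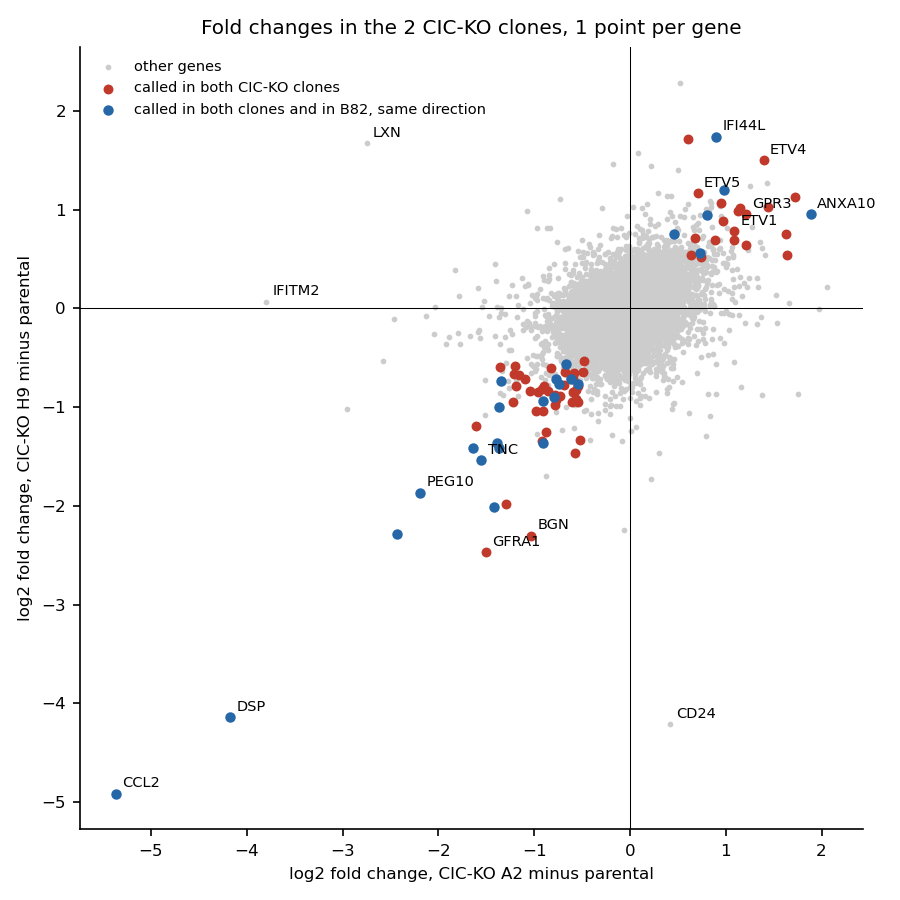
Log2 fold change against parental cells in CIC-KO A2 (x axis) and CIC-KO H9 (y axis), 1 point per gene, with the 83 genes called the same way in both clones in red or blue and, of these, the 25 also called that way in ATXN1L-KO B82 in blue. CCL2 (-5.37 and -4.91) and DSP (-4.18 and -4.14) lie far from the other genes on the diagonal, while LXN, IFITM2 and CD24 lie off it.

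The list of reported CIC targets, compiled from published knowledge, had 22 measured members. In the mean of the clones 7 were called higher, 0 lower and 15 were not called, and 8 were higher when adjusted over the list alone. Of these, SHC3 was called in A2 (1.21, adjusted p = 8.71e-05) and ran the other way in H9 (-0.14, adjusted p = 0.731). Its mean (0.53, adjusted p = 0.0223) was not called without parental replicates 1 or 3 (0.0768 and 0.0946), A2 replicate 2 (0.0535) or H9 replicate 3 (0.0543), with the neighbouring-gene trend removed (0.067) or with only the arrays compared (0.0508). The list passed the set test (camera, adjusted p = 4.11e-05) with the preset correlation, and had adjusted p = 0.194 with an estimated correlation. Its mean log2 fold change was 0.30 and its median 0.08. ETV1 rose 1.91-fold (0.94 ± 0.15, adjusted p = 0.00464), ETV5 1.92-fold (0.94 ± 0.13, adjusted p = 0.0013) and SPRY4, an inhibitor of ERK signalling, had a log2 fold change of 0.73 ± 0.10 (adjusted p = 0.00139). In single clones, ETV5 was called in A2 at adjusted p = 0.0148, but not without parental replicate 3 (0.0682) or A2 replicate 1 (0.0502), or with only the arrays compared (0.0804). ETV1 was called in H9 at adjusted p = 0.0339, but not without parental replicates 2 or 3, A2 replicate 2, H9 replicates 1, 2 or 3, or B82 replicates 2 or 3 (from 0.0507 to 0.152). It was not called there with only the arrays compared (0.133), a replicate block (0.0563) or arrays centred on their median (0.0503). SPRY4 was not called in H9 (0.45, adjusted p = 0.0725). The ERK phosphatase gene DUSP6 was called in the mean (0.64, adjusted p = 0.0331), but not without any parental replicate (0.0571 to 0.126), A2 replicates 1 or 2 (0.0573 and 0.0706) or H9 replicates 1 or 2 (0.0756 and 0.0769), or with only the arrays compared (0.0732).

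All MAPK activity score genes are also on the list of reported CIC targets, so this list is not a separate finding. It had 4 of 9 members called higher and 0 lower, with the same 4 and 0 adjusted over the list alone (ETV4, ETV5, SPRY4 and DUSP6 among its members). It passed at adjusted p = 0.000158 (adjusted p = 0.272 with an estimated correlation). Without any parental replicate, DUSP6 was not called in the mean (0.0571 to 0.126). Unfolded protein and integrated stress response genes had 0 of 13 called over all genes by limma (6 higher and 0 lower at an unadjusted p under 0.05) and 2 higher and 0 lower adjusted over the list alone. That list passed upwards at adjusted p = 0.000514 (adjusted p = 0.523 with an estimated correlation), and without parental replicate 2 it had 4 members called higher.

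Of the lists that passed downwards in the mean of the clones, fibrillar collagens and matrix had 4 of 14 members called lower and 1 higher (8 and 1 adjusted over the list alone), at adjusted p = 1.65e-05 (adjusted p = 0.191 with an estimated correlation). The lower members include BGN and TNC, called in both clones, and LOXL1 (-1.09, adjusted p = 0.00464), which was called in A2 (-1.89, adjusted p = 0.00011) and not in H9 (-0.29, adjusted p = 0.655). The higher one is VCAN, called in H9 (0.80, adjusted p = 0.00287) and not in A2 (0.13, adjusted p = 0.643), whose 2 probe sets differ in sign and whose call ended with their mean (0.389). VCAN was also not called without any parental replicate (0.0732 to 0.105), A2 replicates 1 or 2 (0.0568 and 0.056), H9 replicates 1 or 2 (0.0775 and 0.064) or B82 replicates 1 or 2 (0.0509 and 0.0523), nor with a replicate block (0.0535) or only the arrays compared (0.078). Mitosis genes had 3 of 22 called lower and 0 higher (7 and 0 adjusted over the list alone), at adjusted p = 6.02e-05 (adjusted p = 0.121 with an estimated correlation). All 3 were called in A2 and none in H9, where KIF20A had a log2 fold change of -0.19 (adjusted p = 0.574) and CCNB2 one of -0.24 (adjusted p = 0.553). In the mean, KIF20A (-0.53, adjusted p = 0.012) was not called without parental replicate 3 (0.0563) or with the neighbouring-gene trend removed (0.0773). CCNB2 (-0.52, adjusted p = 0.0364) was called without A2 replicate 1 or B82 replicate 1 but not without any other array (0.0505 to 0.138), and not with that trend removed (0.0769), a replicate block (0.066) or only the arrays compared (0.0749). The count of 3 was 1 without parental replicate 2, A2 replicate 2 or H9 replicates 1 or 3, and 0 without parental replicate 3. Inflammatory cytokine genes had 5 of 20 called lower and 1 higher (5 and 2 adjusted over the list alone), at adjusted p = 0.0199 (adjusted p = 0.453 with an estimated correlation). They include CCL2 and CXCL5 (-0.93, adjusted p = 0.00074), called in both clones, and VCAM1 (-1.99 ± 0.36, adjusted p = 0.00999), which was called in A2 (-2.96, adjusted p = 0.000918) and not in H9 (-1.01, adjusted p = 0.312). CXCL5 was not called in A2 without any parental replicate, A2 replicates 2 or 3, H9 replicates 1 or 3 or B82 replicates 1 or 2 (0.051 to 0.168), nor with centred arrays (0.0583), the trend removed (0.065), a replicate block (0.07) or only the arrays compared (0.138). The parental arrays of VCAM1 read 6.56, 8.31 and 6.14 and its H9 arrays 6.12, 5.86 and 5.99, while the higher one, CCL20 (0.66, adjusted p = 0.0492), was called with parental replicate 3 left out but with no other array left out (0.0561 to 0.199), and not with centred arrays (0.0583), the trend removed (0.0619), a replicate block (0.0739) or only the arrays compared (0.0868). The list did not pass without parental replicate 2 (0.143), A2 replicate 1 (0.0542) or H9 replicate 2 (0.0501), or with array weights (0.146). Neural stem cell markers had 3 of 16 called lower and 0 higher, the same adjusted over the list alone. They were TNC and SOX4, called in both clones, and PAX6, called in A2 (-1.67, adjusted p = 1.65e-05) and not in H9 (-0.28, adjusted p = 0.463). SOX4 was not called in H9 without any H9 replicate (0.0583 to 0.0794) or with only the arrays compared (0.0685). The list passed at adjusted p = 0.0112 (adjusted p = 0.453 with an estimated correlation), and did not pass without A2 replicate 1 (0.0735). YAP/TAZ targets had 1 of 13 called lower and 0 higher (4 and 1 adjusted over the list alone), with 0 called lower without parental replicates 1 or 3 or any H9 replicate. This list passed at adjusted p = 0.0217 (adjusted p = 0.255 with an estimated correlation), and did not pass without H9 replicate 2 (0.0501). It did not pass with array weights (0.0503), quantile normalization (0.064), the lowest 50% of genes dropped (0.0857) or the neighbouring-gene trend removed (0.0984). Hypoxia and glycolysis genes had 0 of 14 called by limma, with 5 lower at an unadjusted p under 0.05 (2 lower and 0 higher adjusted over the list alone), at adjusted p = 0.0082 (adjusted p = 0.53 with an estimated correlation), and did not pass without parental replicate 2 (0.429), with array weights (0.139) or with the lowest 50% of genes dropped (0.0553). In all, 9 of 32 lists passed in the mean of the clones with the preset correlation, and 0 with camera's estimated correlation, where 5 had an unadjusted p under 0.05 and where fry passed 8.

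The direct comparison of H9 with A2 asks how far a pair of clones of the same genotype differ. LXN, which encodes the protease inhibitor latexin, was 21.4-fold higher in H9 than in A2 (4.42 ± 0.21 SE, adjusted p = 4.54e-08), at -2.75 in A2 and 1.67 in H9. IFITM2, an interferon-induced membrane protein gene, was 14.6-fold higher in H9 (3.86 ± 0.15, adjusted p = 7.23e-09), and its value in A2 was 13.9-fold below the parental line. CD24, a surface glycoprotein gene, was 24.6-fold lower in H9 than in A2 (-4.62 ± 0.21, adjusted p = 2.63e-08), at 0.41 in A2 (adjusted p = 0.319) and -4.21 in H9. The lower arm is dim for LXN (1.89 to 2.93 in A2), CD24 (3.11 to 3.74 in H9) and IFITM2 (4.24 to 4.52 in A2), so the size of these folds is uncertain. Called were 832 genes, 471 higher and 361 lower in H9, 152 of them at least 2-fold. The count was 512 without A2 replicate 2, 514 without H9 replicate 1 and 438 without H9 replicate 2. The 832 exceeds the 731 of A2 and the 297 of H9 against the parental line. The count of A2 was larger without H9 replicate 1 (514 against 619), H9 replicate 2 (438 against 615) or H9 replicate 3 (576 against 668). These are arrays that A2 against the parental line does not use. Without A2 replicates 1, 2 or 3, which both contrasts use, H9 against A2 stayed larger (658 against 636, 512 against 380 and 630 against 437).

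Of 32 lists, 4 passed for H9 against A2. Receptor tyrosine kinases and growth factors had 6 of 25 members called lower and 0 higher (9 and 1 adjusted over the list alone), at adjusted p = 0.000126, and passed also at adjusted p = 0.0392 with an estimated correlation. NRG1 (-1.02, adjusted p = 0.000988), FGF5 (-1.06, adjusted p = 0.000439) and MET (-0.85, adjusted p = 0.00296) were among them, and 1 member was called higher without A2 replicate 1. Cholesterol synthesis genes had 2 of 16 called lower and 0 higher (11 and 0 adjusted over the list alone), at adjusted p = 0.0001 (adjusted p = 0.393 with an estimated correlation), with SQLE at -0.62 (adjusted p = 0.00761). The other, HMGCS1 (-0.54, adjusted p = 0.0382), was not called without parental replicates 1 or 3, A2 replicates 1 or 2, any H9 replicate or B82 replicates 1 or 2 (0.0512 to 0.154), nor with centred arrays (0.0535), a replicate block (0.0648) or only the arrays compared (0.097), and 5 members were called lower without parental replicate 2. Cytosolic ribosomal protein genes had 2 of 19 called higher and 0 lower (8 and 0 adjusted over the list alone), at adjusted p = 4.63e-05 (adjusted p = 0.64 with an estimated correlation). They were RPS23 (0.75, adjusted p = 0.00376) and RPS6 (0.39, adjusted p = 0.0484), and neither was called with the neighbouring-gene trend removed (0.131 and 0.468). RPS6 was called with parental replicate 2 left out but with no other array left out (0.0575 to 0.149), and not with quantile normalization (0.0663), a replicate block (0.0886) or only the arrays compared (0.0869). Unfolded protein and integrated stress response genes had 1 of 13 called lower, ASNS (-0.79, adjusted p = 0.00674), and 0 higher (3 and 0 adjusted over the list alone), at adjusted p = 0.0425 (adjusted p = 0.662 with an estimated correlation). That list did not pass without A2 replicate 1 (0.105), A2 replicate 2 (0.139), H9 replicate 3 (0.0892) or B82 replicate 1 (0.0506), nor with the lowest 50% of genes dropped (0.0819) or the neighbouring-gene trend removed (0.0678), and had 3 members called lower without parental replicate 2. Without A2 replicate 3, 8 lists passed.

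Against the parental line, 11 lists passed in A2 and 8 in H9 with the preset correlation, but 0 in each with camera's estimated correlation (adjusted p from 0.112 to 0.429 for the 11 and from 0.245 to 0.619 for the 8). There 6 and 5 had an unadjusted p under 0.05, and fry passed 14 and 7. In H9, 5 passed without parental replicate 1 and 4 without parental replicate 3. In both clones reported CIC targets and their subset of MAPK activity score genes passed upwards, and mitosis and fibrillar collagens and matrix downwards. In H9, reported CIC targets did not pass without parental replicate 3 (0.0852), MAPK activity score genes without parental replicates 1 or 3 (0.114 and 0.0911) or with only the arrays compared (0.0775), and mitosis without parental replicates 1 or 3 (0.114 and 0.0931), H9 replicate 3 (0.0717) or the lowest 50% of genes (0.0781). Receptor tyrosine kinases and growth factors passed in opposite directions, upwards in A2 (adjusted p = 0.0338, 3 of 25 called higher and 2 lower) and downwards in H9 (adjusted p = 0.0368, 0 called higher and 1 lower). In A2 that list did not pass without parental replicate 1 (0.0751), A2 replicates 1 or 2 (0.0982 and 0.0654), the lowest 30% of genes (0.0537) or the neighbouring-gene trend (0.0805), and in H9 without parental replicates 1 or 3 (0.0766 and 0.124), H9 replicates 2 or 3 (0.0681 and 0.054) or the lowest 50% of genes (0.0676). The 2 lower members in A2 became 1 without parental replicate 1 or A2 replicate 2 and 0 without parental replicate 3 or A2 replicate 3, and the 1 in H9 became 0 without parental replicates 1 or 3 or H9 replicates 1 or 3.

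Further lists passed in A2 and missed the threshold in H9, upwards for unfolded protein and integrated stress response genes, and downwards for hypoxia and glycolysis, neural stem cell markers, fibroblast and mesenchymal markers, cytosolic ribosomal proteins and mitochondrial respiratory chain. Fibroblast and mesenchymal markers, which thus moved with the matrix genes in A2, had 5 of 15 members called lower and 1 higher (adjusted p = 0.0208, and adjusted p = 0.138 with an estimated correlation). TAGLN (-1.92, adjusted p = 0.00011) and SNAI2 (-1.58, adjusted p = 0.000403) were called in A2, against -0.36 and -0.21 in H9, where neither was called. That list did not pass without parental replicate 1 (0.0591), with quantile normalization (0.0554) or with the lowest 30% or 50% of genes dropped (0.0968 and 0.0609). Neural stem cell markers did not pass in A2 without A2 replicate 1 (0.105). Mitochondrial respiratory chain genes did not pass there without parental replicate 2 (0.221) or A2 replicates 2 or 3 (0.0694 and 0.0623), nor with 6 other settings (0.0631 to 0.118). Inflammatory cytokine genes, YAP/TAZ targets and cholesterol synthesis genes passed downwards in H9 and missed the threshold in A2. By the direct test of H9 against A2, only the stress response, ribosomal protein and cholesterol synthesis lists of these 9 passed. The others did not, with adjusted p = 0.0679 for each of hypoxia and glycolysis, fibroblast markers and inflammatory cytokines, 0.264 for neural stem cell markers, 0.211 for the respiratory chain and 0.462 for YAP/TAZ targets, so no difference between the clones was shown for them.

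The comparison of B82 with parental cells asks which genes change when ATXN1L is targeted. CD24 was 20.7-fold lower in B82 (log2 fold change -4.37 ± 0.21 SE, n = 3 arrays per group, adjusted p = 1.11e-07) and CCL2 11.3-fold lower (-3.50 ± 0.28, adjusted p = 1.88e-05). MYOCD, a muscle transcriptional coactivator gene, was 6.93-fold lower (-2.79 ± 0.18, adjusted p = 2.18e-06), and the kinase gene CDK14 was 5.83-fold lower (-2.54 ± 0.13, adjusted p = 1.31e-07). PARD6B, which encodes a cell polarity protein, was 4.2-fold higher (2.07 ± 0.21, adjusted p = 0.000152), and GPC6, which encodes a cell surface proteoglycan, 2.55-fold higher (1.35 ± 0.12, adjusted p = 4.64e-05). The Notch ligand gene JAG1 had a log2 fold change of -1.58 ± 0.12 (adjusted p = 9.93e-06). CD24 is dim in B82 (3.04 to 3.53), and CCL2 (4.51 to 4.59) and CDK14 (4.59 to 4.92) lie close to the array medians, so the size of these folds is uncertain. These 7 genes were called in B82 without any single array. With 1 clone, a difference carried by the clone cannot be separated from the knockout.

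In B82, 228 genes were called, 67 higher and 161 lower, 62 of them at least 2-fold. The count fell to 100 without parental replicate 3 and to 94, 97 and 144 without B82 replicates 1, 2 and 3. No reported CIC target was called in B82 (limma, 0 of 22 members, and 0 adjusted over the list alone), and the list did not pass camera (adjusted p = 0.54). At an unadjusted p under 0.05, 4 of its members were higher and 3 lower. ETV4 (0.02, adjusted p = 0.981), ETV5 (0.10, adjusted p = 0.847), GPR3 (0.12, adjusted p = 0.833) and ETV1 (0.40, adjusted p = 0.331) were not called there.

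Of 32 lists, 8 passed in B82, and 0 with camera's estimated correlation, where 5 had an unadjusted p under 0.05 and where fry passed 10. Fibrillar collagens and matrix had 2 of 14 members called lower and 0 higher (9 and 0 adjusted over the list alone), at adjusted p = 4.42e-08 (adjusted p = 0.0722 with an estimated correlation). They were TNC, at -1.58 ± 0.14 (adjusted p = 4.64e-05), and FBN1, at -0.65 (adjusted p = 0.0215), which was not called without parental replicates 2 or 3 (0.0549 and 0.076) or B82 replicates 1 or 2 (0.0674 and 0.116). TGF-beta targets had 2 of 11 called lower and 0 higher (7 and 1 adjusted over the list alone), at adjusted p = 0.000508 (adjusted p = 0.0722 with an estimated correlation). They were TAGLN (-1.13, adjusted p = 0.0153), not called without B82 replicates 2 or 3 (0.0768 and 0.057), and LTBP1 (-0.87, adjusted p = 0.0188), not called without B82 replicates 1 or 2 (0.0814 and 0.0964). YAP/TAZ targets had 0 of 13 called by limma, with 6 lower at an unadjusted p under 0.05 (4 lower and 0 higher adjusted over the list alone), at adjusted p = 0.000648 (adjusted p = 0.0787 with an estimated correlation). DNA replication genes had 0 of 23 called, with 5 lower at an unadjusted p under 0.05 (1 lower and 0 higher adjusted over the list alone), also at adjusted p = 0.000648 (adjusted p = 0.51 with an estimated correlation), and did not pass without parental replicate 2 (0.0647). Called lower were 2 YAP/TAZ targets without parental replicate 2 and 1 without A2 replicates 2 or 3, and 1 DNA replication gene without parental replicate 1.

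Interferon response genes had 2 of 21 called higher in B82 and 0 lower (2 and 1 adjusted over the list alone), at adjusted p = 0.00604 (adjusted p = 0.149 with an estimated correlation). They were IFI44L (1.48 ± 0.21, adjusted p = 0.00276) and XAF1 (0.70, adjusted p = 0.0255), which was not called without parental replicates 1 or 3 (0.0634 and 0.108) or B82 replicates 1, 2 or 3 (0.0939, 0.116 and 0.056). Hypoxia and glycolysis genes had 0 of 14 called by limma, with 7 lower at an unadjusted p under 0.05 (6 lower and 0 higher adjusted over the list alone), at adjusted p = 0.0117 (adjusted p = 0.51 with an estimated correlation), and did not pass without parental replicate 2 (0.28) or with array weights (0.108), while 2 were called lower without parental replicate 1. Notch pathway genes had 2 of 24 called lower and 0 higher (4 and 0 adjusted over the list alone), at adjusted p = 0.0169 (adjusted p = 0.349 with an estimated correlation), and did not pass without B82 replicate 3 (0.0647). They were JAG1 and NOTCH1 (-0.63), and the latter was not called without parental replicates 2 or 3 (0.0728 and 0.0907), H9 replicates 1 or 2 (0.051 and 0.0506) or any B82 replicate (0.0674 to 0.15). ERK phosphatases and feedback inhibitors had 2 of 16 called lower and 0 higher, the same adjusted over the list alone, at adjusted p = 0.0217 (adjusted p = 0.349 with an estimated correlation), and did not pass without parental replicate 2 (0.0647) or B82 replicate 2 (0.0876), nor with array weights (0.0544), quantile normalization (0.0536) or the lowest 30% or 50% of genes dropped (0.0629 and 0.0755). They were DUSP1 (-0.60) and DUSP7 (-0.58). DUSP1 was not called without parental replicates 1 or 3 or B82 replicates 1 or 2 (0.0802 to 0.139), and DUSP7 without parental replicates 2 or 3, H9 replicate 1 or any B82 replicate (0.0502 to 0.106). With only the arrays compared, FBN1, TAGLN, LTBP1, NOTCH1, XAF1, DUSP1 and DUSP7 were not called in B82 (0.0668 to 0.133). NOTCH1 and DUSP7 were also not called there with the neighbouring-gene trend removed (0.0523 and 0.0746).

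The other lists passed neither in the mean of the CIC-KO clones nor in B82, with adjusted p given in that order. They were the CIC complex (0.37 and 0.0734), ETS family (0.548 and 0.996), immediate early genes (0.279 and 0.391), RAS-MAPK core components (0.363 and 0.874) and p53 targets (0.0999 and 0.54). MHC class I and antigen processing (0.37 and 0.54), matrix proteases (0.644 and 0.937), Wnt targets (0.934 and 0.944) and mitochondrial respiratory chain (0.097 and 0.937) did not pass either. Of these, MHC class I was tested on 5 of 17 members and the respiratory chain on 8 of 29. Nor did receptor tyrosine kinases and growth factors (0.919 and 0.309), cholesterol synthesis (0.258 and 0.0696) and cytosolic ribosomal proteins (0.135 and 0.44) in these contrasts. Among the cell type markers these were astrocyte (0.232 and 0.471), oligodendrocyte (0.351 and 0.728), neuron (0.232 and 0.391), fibroblast (0.0608 and 0.146), microglia and blood cell (0.96 and 0.471) and endothelial markers (0.279 and 0.874). For matrix proteases in the CIC-KO mean the mean log2 fold change (-0.02) and the median (0.05) differ in sign, and for neuron markers the mean (0.07) and the median (-0.01) do, with the test upwards in both.

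The direct comparison of B82 with the mean of the CIC-KO clones asks where the knockouts differ. ETV4 was 2.69-fold lower in B82 (-1.43 ± 0.14 SE, adjusted p = 5.84e-05), ETV5 1.78-fold lower (-0.83 ± 0.13, adjusted p = 0.00222) and GPR3 1.95-fold lower (-0.96 ± 0.14, adjusted p = 0.00161). ETV1 was not called (-0.53, adjusted p = 0.0654). CDK14 was 11.1-fold lower (-3.47 ± 0.11, adjusted p = 5.94e-10), since it was higher in the CIC-KO clones (0.92) and lower in B82, and CCN3 was 5.42-fold lower (-2.44 ± 0.14, adjusted p = 9.54e-07). DSP was 7.26-fold higher in B82 than in CIC-KO (2.86 ± 0.24, adjusted p = 1.47e-05), CCL2 3.11-fold higher (1.64 ± 0.24, adjusted p = 0.00166) and GFRA1 3.27-fold higher (1.71 ± 0.18, adjusted p = 8.66e-05). ATXN1, which encodes the paralog of ATXN1L, had a log2 fold change of -0.78 ± 0.16 (adjusted p = 0.0154), but was not called without B82 replicate 1 (0.106) or B82 replicate 2 (0.0584).

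Called were 702 genes, 365 higher and 337 lower in B82, 85 of them at least 2-fold. The count fell to 310, 291 and 396 without B82 replicates 1, 2 and 3. Of 32 lists, 7 passed, and 0 with camera's estimated correlation, where 2 had an unadjusted p under 0.05 and where fry passed 8. Reported CIC targets had 6 of 22 called lower and 0 higher (8 and 1 adjusted over the list alone), at adjusted p = 0.00293 (adjusted p = 0.376 with an estimated correlation). Of these, EPHA2 (-0.60, adjusted p = 0.0384) was not called without A2, H9 or B82 replicates 1 or 2 (0.0636 to 0.189), with centred arrays (0.0515), a replicate block (0.0561) or the neighbouring-gene trend removed (0.0661). Without A2 replicate 1, 1 member of this list and 1 MAPK activity score gene were called higher. All MAPK activity score genes are members of the list of reported CIC targets. MAPK activity score genes had 5 of 9 called lower and 0 higher (5 and 1 adjusted over the list alone), at adjusted p = 0.000501 (adjusted p = 0.376 with an estimated correlation), with SPRY4 at -1 ± 0.10 (adjusted p = 6.44e-05) and DUSP6 at -0.79 ± 0.14 (adjusted p = 0.00645). TGF-beta targets had 3 of 11 called lower and 0 higher (5 and 0 adjusted over the list alone), at adjusted p = 0.000149 (adjusted p = 0.06 with an estimated correlation), with LTBP1 at -1.52 ± 0.14 (adjusted p = 3.66e-05). Interferon response genes had 3 of 21 called higher and 0 lower (5 and 0 adjusted over the list alone), at adjusted p = 0.00239 (adjusted p = 0.177 with an estimated correlation), and did not pass with the lowest 50% of genes dropped (0.11). They had 1 called higher without B82 replicates 2 or 3. Unfolded protein and integrated stress response genes had 4 of 13 called lower and 0 higher, the same adjusted over the list alone, at adjusted p = 0.00248 (adjusted p = 0.641 with an estimated correlation), with 1 called lower without B82 replicates 1 or 2. Cholesterol synthesis genes had 5 of 16 called higher and 0 lower, the same adjusted over the list alone, at adjusted p = 0.00321 (adjusted p = 0.436 with an estimated correlation), with MSMO1 at 0.78 (adjusted p = 0.00308). The count was 3 without parental replicate 3, A2 replicates 1 or 3, any H9 replicate or B82 replicate 2, 2 without B82 replicate 1 and 1 without B82 replicate 3. DNA replication genes had 1 of 23 called lower and 0 higher, the same adjusted over the list alone, at adjusted p = 0.0315 (adjusted p = 0.697 with an estimated correlation), with 2 called lower without parental replicate 2 and 0 without any B82 replicate. That list did not pass without A2 replicates 1 or 2 (0.0777 and 0.0518), H9 replicates 1 or 2 (0.055 and 0.0548) or B82 replicate 2 (0.0722), nor with the lowest 30% or 50% of genes dropped (0.0609 and 0.0922).

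The overlap of the lines asks which changes the clones edited in CIC and the clone edited in ATXN1L have in common. Called in the same direction in A2, H9 and B82 were 25 genes, 6 higher and 19 lower, of which 0 higher and 9 lower genes changed at least 2-fold in each line (limma). The overlap was 13 without parental replicate 3, 13 without B82 replicate 1 and 15 without B82 replicate 2. CCL2, TNC, NPR3, PEG10, ANXA3 and CRISPLD2 were lower and FLRT2 higher in all 3 lines without any single array. TNC had nearly equal log2 fold changes of -1.55 in A2, -1.54 in H9 and -1.58 in B82, and B82 differed from CIC-KO by -0.04 ± 0.12 (adjusted p = 0.914). DSP was called in B82 (-1.30, adjusted p = 0.0345), but not without parental replicates 1 or 3 (0.0906 and 0.122) or B82 replicates 1, 2 or 3 (0.113, 0.133 and 0.0809), or with the neighbouring-gene trend removed (0.0614). Of the 83 genes called in both CIC-KO clones, 55 were not called in B82, and CDK14, CCN3 and MCOLN3 were called there in the opposite direction. The call of MCOLN3 in B82 was lost without parental replicate 3 (0.0596), B82 replicate 1 (0.0519) or B82 replicate 2 (0.0529), and its call in H9 without A2 replicate 3 (0.0509), any H9 replicate (0.0917 to 0.155) or any B82 replicate (0.0566 to 0.0602). With only the arrays compared MCOLN3 was called in none of the lines (0.0688 to 0.147), and with the neighbouring-gene trend removed it was not called in H9 (0.0598). By the direct test, 45 of the 83 differed between B82 and CIC-KO, against 702 of all 14884 genes. The 83 were picked through the CIC-KO arrays that this test also uses, which can enlarge their difference from B82. The 45 thus does not measure how far the knockouts differ. Of the 228 genes called in B82, 70 were called the same way in A2, 48 in H9 and 116 in neither.

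All 3 knockout lines were compared with the same 3 parental arrays, which makes their fold changes correlate even where nothing changed. In 100 simulations of unchanged groups, limma called 0 genes in both clones and 0 in all 3 lines, against 83 and 25 observed. With no changed genes few calls can arise in any contrast, so these zeros do not measure how far shared arrays raise the overlap of lists with real changes. Independent lists of the same sizes would share 1.43 higher and 6.88 lower genes between the clones, against 25 and 58 observed. For all 3 lines, the genes called in both clones were taken as given and as independent of the B82 calls. They would then share 0.113 higher and 0.627 lower genes with B82, against 6 and 19 observed. Across genes, which are not independent replicates, the covariance of the log2 fold changes of A2 and H9 was 0.0361, against a simulated mean of 0.0184. That of the CIC-KO mean and B82 was 0.0291, against 0.0184. The correlations, by contrast, were lower than in the simulations of unchanged groups, with r = 0.435 for A2 and H9 (simulated mean 0.499, from 0.478 to 0.519) and r = 0.451 for the CIC-KO mean and B82 (simulated mean 0.577, from 0.563 to 0.598). The simulations gave every array a gene's pooled spread, while the shared part comes from the parental arrays alone. Parental replicates 1, 2 and 3 had residual SDs of 0.196, 0.247 and 0.174, and replicate 2 had the largest of all arrays. The simulated covariances may thus be too low. The 3 parental arrays are too few to split between the contrasts, so part of the excess over independent lists may come from the shared controls.

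Neighbouring genes shifted together in each knockout line. In the order of GRCh38.p14, A2 had 8 runs in which the running median of the log2 fold change stayed beyond 0.2, H9 had 3 and B82 had 3, against 0 in any of 100 shuffles of the gene order. In A2 they lie on chromosomes 2, 5, 11 and 15 and are all lower, with medians from -0.35 (chromosome 5, MCIDAS to LINC01554) to -0.23 (chromosome 2, CGREF1 to VAMP5). In H9 they lie on chromosomes 1 and 7, with medians of -0.30 (OLFML2B to TIMM17A), -0.29 (MIR3122 to PGBD2) and -0.24 (STEAP1B to CHCHD2). In B82 they lie on chromosome 10 (HNRNPH3 to EEF1AKMT2, -0.29), chromosome 13 (CCDC70 to CHAMP1, 0.31) and chromosome 16 (CNGB1 to MTHFSD, -0.28), the last of which holds ATXN1L. The runs hold 9.49% of genes and 25.4% of the calls in A2, 3.27% and 15.2% in H9, and 4.33% and 18.4% in B82. With this trend removed, the count of called genes was 479 in A2, 209 in the mean of the CIC-KO clones and 148 in B82.

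**Figure D3:**
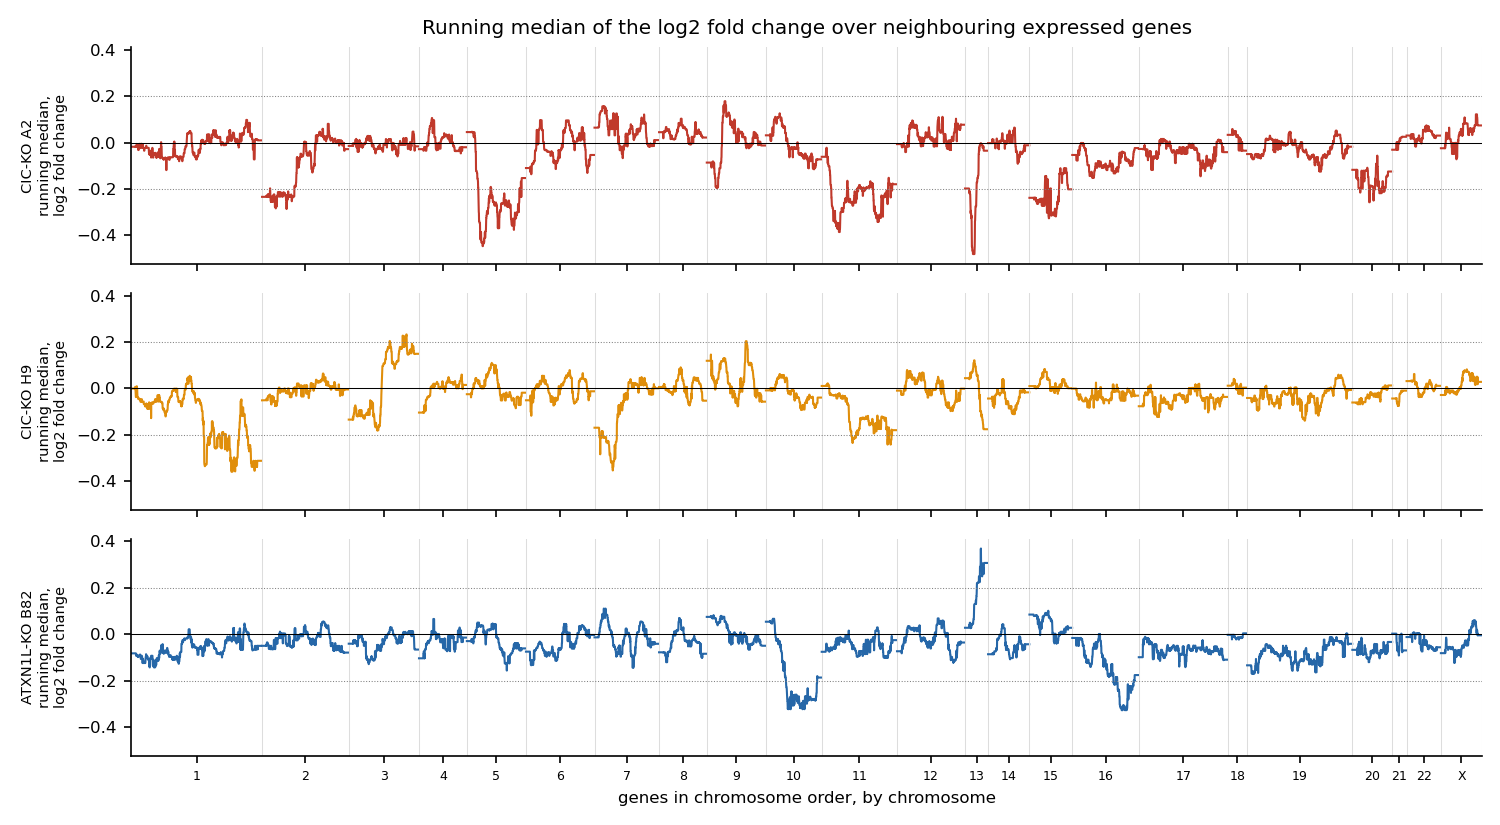
Running median of the log2 fold change against parental cells over 61 neighbouring expressed genes (y axis), with genes in GRCh38.p14 order by chromosome (x axis), for CIC-KO A2, CIC-KO H9 and ATXN1L-KO B82 from top to bottom, and dotted lines at -0.2 and 0.2. Long stretches lie beyond the dotted lines in a single line each, such as chromosome 5 in A2, chromosome 1 in H9 and chromosome 13 in B82.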

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

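The tests of explanations and the counts of other splits given here were set up after the results had been seen, while the direct test of H9 against A2 was planned.

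Differences between the clones of the same genotype stand out, by the direct test of H9 against A2 in limma. The log2 fold change of H9 minus that of A2 was 4.42 for LXN, 3.86 for IFITM2, 2.35 for DNAAF9, 2.21 for IL7R, 2.06 for LINC03033, and 2.05 for each of MBOAT1, ZNF215 and PLEK2. It was -4.62 for CD24, -2.63 for LOC100507412, -2.26 for NEGR1, -2.18 for TFAP2C, -2.09 for HHIP, -1.97 for TMEM71, -1.96 for NETO1 and -1.94 for PCDH7. Genes changed the same way in both clones also differed in size, with 1.11 for PRUNE2, 0.84 for IFI44L, -1.27 for BGN, -1.10 for ANTXR2, -0.96 for GFRA1, -0.93 for ANXA10, -0.87 for CDCP1 and -0.59 for NPR3. Not all of these were called in both clones under every setting. PRUNE2 was not called in A2 without parental replicates 1 or 3 or A2 replicates 1 or 2 (0.0713 to 0.11), with the neighbouring-gene trend removed (0.117) or with only the arrays compared (0.118). IFI44L was not called in A2 without parental replicate 2 or A2 replicates 1 or 2 (0.0806 to 0.0921) or with only the arrays compared (0.0953). ANTXR2 was not called in H9 without parental replicates 1 or 3 or any H9 replicate (0.0637 to 0.0995) or with only the arrays compared (0.0838). CDCP1 was not called in H9 without parental replicates 1 or 3 or H9 replicates 1 or 2 (0.0631 to 0.0901) or with only the arrays compared (0.0977). Among reported CIC targets it was 0.62 for MYC, -1.35 for SHC3, -0.76 for EPHA2, -0.72 for DUSP4, -0.69 for IER3 and -0.56 for SPRY4. IER3 has 11 probe sets, which differ in sign in CIC-KO.

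Several of these differences were not called without single arrays. For IFI44L these were A2 replicates 2 and 3 and H9 replicates 1 and 2 (adjusted p from 0.0674 to 0.123), for GFRA1 A2 replicate 3 (0.0542) and H9 replicate 2 (0.0774), and for SPRY4 H9 replicate 2 (0.0568). For EPHA2 they were A2 replicates 1 and 2 and H9 replicates 2 and 3 (0.0713 to 0.0833), and for MYC A2 replicate 3 and H9 replicates 1, 2 and 3 (0.0628 to 0.0834). For NPR3 they were parental replicate 3, A2 replicates 1 and 3 and every H9 and B82 replicate (0.0502 to 0.129), and for DUSP4 parental replicate 3 and every A2, H9 and B82 replicate (0.0594 to 0.139). The difference of NPR3 was -0.32 with array weights (0.119), and was not called with the neighbouring-gene trend removed (0.0714) or with only the arrays compared (0.117), nor was that of DUSP4 with the trend removed (0.0833). Among gene lists, the mean difference of H9 minus A2 was -0.29 for receptor tyrosine kinases and growth factors, -0.32 for cholesterol synthesis, -0.22 for the unfolded protein and integrated stress response and 0.30 for cytosolic ribosomal proteins. The stress response list did not pass without A2 replicate 1 (0.105), A2 replicate 2 (0.139), H9 replicate 3 (0.0892) or B82 replicate 1 (0.0506).

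Of the 37519 probe sets without a single gene symbol, which the comparisons of genes do not use, 427 were called in A2, 116 in H9, 92 in B82 and 40 in both CIC-KO clones in the same direction. In that fit p was adjusted over all probe sets, of which 789, 245, 167 and 79 were called in this order. What they measure was not examined.

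The 14 runs of neighbouring genes that shifted in a single line form the first pattern weighed. The spread of the shared parental arrays would move all 3 lines alike, and in 0 of 14 runs did both other lines reach 50% of the run's own median in its direction, which argues against it. An effect of the CIC knockout would appear in both CIC-KO clones, and in 9 of the 11 runs of A2 and H9 the other clone stayed under 50%. In the other 2 runs, on chromosome 11, the other clone reached it with medians of -0.24 in A2 and -0.21 in H9 for FNBP4 to NRXN2 and, just over 50%, -0.25 in A2 and -0.13 in H9 for RNF169 to UBE4A, so an effect of the CIC knockout stays open there. A candidate explanation for single-line runs is a difference in copy number between clones, which was not tested because no DNA was measured.

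The 25 genes changed the same way in all 3 knockout lines form another pattern. Parental replicate 2 lay farthest from its group, but leaving it out kept the median size of the 25 log2 fold changes at 1.08 against 1.14, a ratio of 0.946, with 17 genes still called the same way in all lines. Removing the trend of chromosome stretches gave a median size of 1.2, a ratio of 1.06, with 16 still called. The median thus stayed close to its value while some calls ended, without parental replicate 2 with 1 parental array fewer. Yet neither ratio could easily have fallen. The 25 were picked as called with all arrays, and a gene moved by parental replicate 2 alone would vary widely and seldom be called. The run medians, between -0.35 and 0.31, are too small to make up changes of that median size. Smaller changes among the 25 stay open to the trend, and the ratio decides nothing about parental replicate 2. Selection and cloning of edited cells cannot be told apart from a shared effect of the knockouts, since the groups include 0 edited clones without a knockout.

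The last pattern is ETV1, ETV4, ETV5 and GPR3, the 4 reported CIC targets called higher in both CIC-KO clones, none of which was called in B82. ETV5 lost its call in A2 without parental replicate 3 (0.0682) or A2 replicate 1 (0.0502), and ETV1 its call in H9 without parental replicates 2 or 3, A2 replicate 2, any H9 replicate or B82 replicates 2 or 3 (0.0507 to 0.152). By the direct test in limma, 3 of the 4 were called lower in B82 than in CIC-KO. They were ETV4 (-1.43, adjusted p = 5.84e-05), ETV5 (-0.83, adjusted p = 0.00222) and GPR3 (-0.96, adjusted p = 0.00161), at 0.02, 0.10 and 0.12 in B82 against the parental line. Selection and cloning shared by all clones would raise B82 too, and these 3 genes were not called higher in this clone. The genes were picked as called in both CIC-KO clones, which can enlarge their difference from B82. The direct test thus does not decide this explanation. With 1 B82 clone and no edited clone without a knockout, it stays open for all 4 genes. ETV1 had a log2 fold change of 0.40 in B82 (direct test in limma, adjusted p = 0.0654). With 1 ATXN1L-KO clone, a difference carried by single clones cannot be told apart from the knockouts for any of the 4. Shifts of chromosome stretches are argued against by the 4 of 4 that stayed called in both clones with the neighbouring-gene trend removed. It stays open whether B82 keeps ATXN1L function, since the only ATXN1L probe set, whose place relative to the edit is not known, had a log2 fold change of -0.12, and a role of its paralog ATXN1 was not tested.

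Other splits of the arrays were counted for each result. For A2 (731 called genes), H9 (297) and B82 (228) against the parental line and for H9 against A2 (832), the highest of the other splits gave 0 genes by limma, and only 1 of 10 splits, the real one, reached the real count. With 10 splits the share cannot go below 0.1. With the 6 CIC-KO arrays as 1 group against the parental arrays, the real split called 93 genes, 3 of 84 splits called as many, and the highest other called 748. With the 3 B82 arrays against the 6 CIC-KO arrays, the real split called 312, 2 of 84 called as many, and the highest other called 775. For genes called in both clones (83), 3 of 100 splits gave as many, with 248 the highest other, and for the overlap of all 3 lines (25), 2 of 100 did, with 106 the highest other. These 4 shares lie under 0.05. Yet most other splits mix the clones, which puts the differences between clones into the residual spread, and the other splits called a median of 0 genes. The splits that called more than the real one set all A2 or all H9 arrays apart, which points to the clones as a structure of the samples. The low shares of these 4 results thus follow in part from the clones, and a difference between single clones stays open.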

How the results depend on the processing

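Removal of the neighbouring-gene trend was chosen after the data had been seen, and the other alternatives were planned. The gene results here are the calls of genes that the naming rule picks, mostly for large changes, and not all calls. No such call and no list reversed its direction in the alternatives run for it. The random block and line means were run for the 130 gene results in the mean or B82 and for no list, and treat and the stricter adjusted p for counts only. Of 469 called results of these named genes, 305 kept their call without each of the 12 arrays, and of 47 list results 29 did. Calls of all genes were less stable. Without parental replicate 3, 396 of the 469 kept their call. Among all calls, 429 of 731 in A2, 159 of 297 in H9 and 96 of 228 in B82 then stayed in the same direction. Counts of called genes are given in the order A2, H9, mean of the CIC-KO clones, B82, H9 against A2, B82 against CIC-KO, both CIC-KO clones and all 3 lines, and were 731, 297, 321, 228, 832, 702, 83 and 25.

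Of the 469 called gene results, 468 kept their call with array weights, 467 with the mean of a gene's probe sets, 466 with trend and robust, 462 with quantile normalization, 450 with centred arrays, 423 with a replicate block, 399 with the neighbouring-gene trend removed and 372 with only the arrays compared. With the lowest 30% or 50% of genes dropped, all 438 and 387 that were still measured did. Of the 130 in the mean or B82, 61 kept it with the cell line as a random block and 0 with line means. Of the 47 list results, 47 kept their call with centred arrays, 43 with quantile normalization, 43 with the trend removed, 41 with array weights, and 42 and 37 with the lowest 30% and 50% of genes dropped.

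Leaving out each array gave 380 to 670, 144 to 317, 173 to 298, 94 to 227, 438 to 1191, 291 to 1045, 48 to 84 and 13 to 23. Each fit then has fewer samples. Lists past camera, in the order of the first 6, ranged over 9 to 11, 4 to 10, 7 to 12, 7 to 9, 3 to 8 and 6 to 8 without single arrays.

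Array weights raised the counts to 2337, 741, 1078, 608, 2318, 1498, 256 and 67, with parental replicate 2 down-weighted to 0.286. Treat against a 1.2-fold change, a stricter test by construction, gave 161, 68, 80, 47, 218, 116, 21 and 9. Fits on only the arrays compared, with fewer residual degrees of freedom, gave 247 in A2, 137 in H9, 199 in the mean, 83 in B82, 37 in both clones and 12 in all 3 lines. An adjusted p under 0.01 left 35 genes in both clones and 12 in all lines, and at least a 2-fold change left 17 and 9. Dropping the lowest 50% of genes, with fewer genes tested, gave 511 in the mean and 367 in B82, and eBayes with trend and robust gave 516 and 405, where the cause was not tested.

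With the cell line as a random block the mean had 88 called genes and B82 62, at a consensus correlation of 0.00823. Only A2 and H9 share a genotype, so this correlation rests on that pair. At so low a value the fit treats arrays of a line as nearly independent, so these counts do not test differences at the level of lines. With line means as single samples, which leaves 1 residual degree of freedom, limma called 0 in the mean and 0 in B82, against 496 and 448 at an unadjusted p under 0.05. A block for replicate number gave 629, 231, 244, 160, 766, 520, 71 and 20. The numbers did not pair the arrays, since only 4 of 18 same-numbered pairs of different groups had a residual r over 0.1, with a median of -0.0167. Single pairs of different groups still reached 0.368 (A2 and H9 replicate 3) and -0.434 (A2 replicate 1 and H9 replicate 3). A factor that crosses the groups and that no fit here models is thus not excluded. Removal of the trend gave 479 in A2, 209 in the mean, 148 in B82 and 16 in all lines, of which 401, 193, 140 and 16 are the same genes. The cause of each ended call was not tested. DSP in B82, for example, went from -1.30 to -1.22, at an adjusted p of 0.0614.

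With camera's estimated correlation 0 lists passed in A2, 0 in H9, 0 in the mean, 0 in B82, 1 in H9 against A2 and 0 in B82 against CIC-KO, where 6, 5, 5, 5, 3 and 2 had an unadjusted p under 0.05. Here fry passed 14, 7, 8, 10, 5 and 8. Quantile normalization and centring of arrays on their median kept every count within 1.5 times, and moved the median log2 fold change of all genes by less than 0.03. The arrays give no background values, so how far dim genes are limited by signal over background could not be measured.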

Other observations

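The comparison of genes that B82 shares with a single CIC-KO clone was chosen after the values had been seen, as were the genes KIF5C, CD9, CD200, EDN1 and KLHL4 and the values at ATXN1L and ATXN1.

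B82 had calls in common with each CIC-KO clone that the other clone lacked. Called the same way in B82 and A2, not so in H9, and different between H9 and A2 by the direct test, were 27 genes, 22 of them lower. Log2 fold changes in A2, H9 and B82 were -2.47, -0.11 and -2.16 for DNAAF9, -1.78, 0.13 and -1.38 for KIF5C, which encodes a kinesin, and -1.59, -0.23 and -1.02 for the tetraspanin gene CD9. They were 0.87, -0.21 and 1.18 for GPNMB, 1.37, -0.09 and 1.15 for TFPI2, and 1.32, -0.15 and 1.02 for CD200. Called the same way in B82 and H9, not so in A2, and different between H9 and A2 were 17 genes, 11 of them lower. These include CD24 (0.41, -4.21 and -4.37), the transcription factor gene TFAP2C (-0.06, -2.24 and -1.96), EDN1, which encodes endothelin (0.44, -1.02 and -1.22), and KLHL4 (0.18, 1.06 and 0.83). The lines are all compared with the same parental arrays, and no number expected without a shared change was set beside the 27 and 17. No explanation of these values was tested.

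ATXN1L lies within the chromosome 16 run in which B82 is lower (CNGB1 to MTHFSD in GRCh38.p14, median -0.28). The running median in B82 at ATXN1L was -0.32, against -0.12 ± 0.14 (SE) for ATXN1L itself, and -0.07 in A2 and -0.03 in H9.

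ATXN1 had log2 fold changes of 0.57 in A2 (adjusted p = 0.11), 0.48 in H9 (adjusted p = 0.299) and -0.26 in B82 (adjusted p = 0.643), none of which was called.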
